A study of Mus musculus with 123 samples.

How the data were processed

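The series measured histone H3 lysine 4 methylation in mouse cells by a droplet-based form of chromatin immunoprecipitation sequencing, in which the chromatin of each cell receives a DNA barcode before cells are pooled for immunoprecipitation. Per the labels, 123 libraries were made: 86 with an antibody against H3K4me2 and 37 with an antibody against H3K4me3. The cells were mouse embryonic stem cells (mESC), mouse embryonic fibroblasts (MEF) and EML cells, a blood progenitor line. The libraries fall into 8 groups by mark, cells, a label of mixed cells and, for H3K4me2 in mESC, the range of barcodes. The largest are H3K4me2 in mESC with 59 libraries in 2 groups of 55 and 4, H3K4me2 in pools of mESC and MEF with 24, and H3K4me3 in pools of mESC and MEF with 19. In these pools mESC and MEF had separate ranges of barcodes. Another 10 H3K4me3 libraries are labelled as a mix of mESC and MEF, with no ranges.

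The values used here came from 3 deposited peak lists of the whole series, named ES1, ES2 and ES3. They are read here as 3 sets of stem cells. The mark, the libraries, the number of cells behind each list and the rule that put cells into a list are not given in the sources used here. If the cells were sorted into the lists by the same profiles from which the peaks were called, differences between the lists are partly set by that sorting. No list could be tied to a group of libraries, so no group of libraries was compared with another. Values per library and per cell were not analysed here. Reads were aligned with Bowtie to the mm9 build, per the submitters' processing notes, with no version of Bowtie. The peak caller is not given in the sources used here.

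Each peak has a chromosome, a start, an end, the coordinates of an inner interval and a score, all as deposited by the authors. The score has no unit in the deposited files and was used as the authors' own value to describe and rank peaks within a list. The inner interval started at the peak's start in every peak and ended at the peak's end in 59.0% of ES1, 62.9% of ES2 and 67.7% of ES3 peaks. The score multiplied by the length of the inner interval was a whole multiple of a single unit per chromosome and list in 100% of peaks, with a tolerance of 0.001. The multiple was taken as the number of reads in the inner interval, and the unit as the base pairs per read on that chromosome. If that unit is the chromosome's length divided by its reads, the units of the 3 lists must stand in ratios of whole numbers. Such ratios were found for all 20 chromosomes, although ratios of whole numbers can be fitted to any units. The search accepted only whole lengths not below the last peak end. It gave lengths, for instance 197195432 bp for chromosome 1, and with them the number of reads per chromosome and list. The lengths lay past the last peak of each chromosome by 1799 to 524171 bp. Only this closeness, which the search did not require, bears on the reading of the unit. The score is therefore treated as read density in the inner interval relative to the mean read density of the chromosome. That 1 unit is 1 read is an assumption, and whether these reads were filtered for duplicates is not given in the sources used here.

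The total came to 2441443 reads for ES1, 2717742 for ES2 and 2439853 for ES3. On simulated scores with known answers the recovery returned 60 of 60 units, the reads of 60226 of 60226 peaks, and the length and totals of 20 of 20 chromosomes. These scores were made without noise by the formula that the recovery inverts. The result checks the code, and not whether the deposited scores follow that formula. Overlaps, shared bases and unions were checked on 20 simulated pairs of lists against a direct count, with 0 errors.

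Peaks of 2 lists were counted as overlapping when they shared at least 1 bp. The overlap that list size alone gives was described by 1000 circular shifts of the first list, each chromosome turned by its own random offset over the span up to the last peak, and again for wide and narrow ES1 peaks. Touching or overlapping peaks of the 3 lists were merged into union regions. Shares have exact (Clopper-Pearson) binomial 95% intervals and reads per peak exact Poisson 95% intervals. All of them cover counting error only. With 1 list per name there are no replicates, so no difference between lists has a p-value, and the spread between cultures or between cells is unknown. Peaks were also divided into deciles by reads.

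The overlap rules, the merging, the shifts and the chromosome shares were fixed before the data were examined, with their alternatives: overlap of at least 50% of both peaks, lists of equal length taken from the top by score, autosomes alone, peaks within 1 kb merged, and the share of covered length in place of the share of peaks. The recovery of reads, the deciles, the classes of wide peaks, the ranking by reads and the regions named in the text were chosen after the data were seen. Named regions are the widest union regions of each combination of lists, the peaks with the most reads in a single list, and the regions that hold a peak among the 10 highest scores of every list. Coordinates are 1-based and on mm9.

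The gene annotation at hand is on GRCm38, and 436 peaks on 9 chromosomes start past the last annotated gene end of their chromosome there, so peaks were not assigned to genes. The planned shares of peaks at promoters, the genes with a promoter peak, the named genes and the 15 fixed gene lists therefore have no values. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with matplotlib 3.10.9 for the figures.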

Results

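The data used here were 3 peak lists, ES1, ES2 and ES3, read as 3 sets of mouse embryonic stem cells, from a series of single-cell profiles of histone H3 lysine 4 methylation, a mark found at active and poised promoters and, in its dimethylated form, also at enhancers. Which form of the mark the lists hold is not given in the sources used here. The comparison between the lists asks how far the regions called as peaks differ among the sets of stem cells. ES1 and ES3 rested on nearly equal numbers of reads, 2441443 and 2439853, and ES2 on more, 2717742, as recovered from the scores. No list has a replicate, and intervals below cover counting error only.

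The 3 lists differed in how many regions were called as peaks. ES1 held 26292 peaks, ES2 21543 and ES3 12391, so ES1 had 2.12 times as many peaks as ES3. Covered length differed more: 64.0 Mb in ES1, 46.7 Mb in ES2 and 22.8 Mb in ES3, or 2.43%, 1.77% and 0.865% of the summed chromosome lengths. The median peak was 1684 bp wide in ES1, 1660 bp in ES2 and 1517 bp in ES3. The lists differed more in their wide domains. Peaks of at least 5 kb numbered 2616 in ES1, 1500 in ES2 and 445 in ES3, which were 9.95%, 6.96% and 3.59% of the peaks. Peaks of at least 10 kb numbered 558, 235 and 44.

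The share of reads that fell inside peaks followed the same order. It was 22.9% in ES1 (95% interval 22.8 to 22.9), 15.9% in ES2 (15.8 to 15.9) and 8.86% in ES3 (8.83 to 8.90), counted over the inner intervals of the peaks. The inner intervals made up 69.2% of the covered length in ES1, 73.8% in ES2 and 79.2% in ES3. Reads in the rest of the peaks were not counted, which the intervals do not reflect. The shares of reads also move with how much was called. The inner intervals covered 44.3 Mb, 34.5 Mb and 18.1 Mb, and the reads per kb within them were 12.6, 12.5 and 12.0. The median peak held 16 reads in ES1, 16 in ES2 and 14 in ES3. The smallest number of reads behind a peak was the same in ES1 and ES3 on 20 of 20 chromosomes, and ranged from 6 on chromosome X to 10.

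Most ES3 peaks lay in regions that were also called in the other lists. Of the ES3 peaks, 86.6% overlapped an ES1 peak and 77.1% an ES2 peak, and 78.1% of ES2 peaks overlapped an ES1 peak. Circular shifts of the same lists gave 4.54% (range 3.39 to 7.22) for ES3 in ES1, 3.49% (2.72 to 8.59) for ES3 in ES2 and 4.81% (3.80 to 6.29) for ES2 in ES1. In the other direction, 61.1% of ES1 peaks overlapped ES2, 37.7% of ES1 peaks overlapped ES3, and 42.7% of ES2 peaks overlapped ES3. Of all bases covered by either list, ES1 and ES2 shared 41.7%, ES2 and ES3 28.3%, and ES1 and ES3 26.0%. These shares depend on the lists' lengths and on the overlap rule. With at least 50% of both peaks required, 41.1% of ES3 peaks matched an ES1 peak, and with the longer lists shortened to 12391 peaks by reads, 56.2% overlapped. With 12391 peaks by score, ES3 overlapped ES2 more often than ES1, 43.8% against 39.7%.

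Merging the lists gave 31580 regions, of which 8271 (26.2%) were called in all 3 lists. A further 8629 regions (27.3%) were found in ES1 alone, 4029 (12.8%) in ES2 alone and 939 (2.97%) in ES3 alone. ES1 and ES2 shared 7501 regions without ES3, more than the 1564 of ES1 and ES3 or the 647 of ES2 and ES3. Regions in all 3 lists were the widest, with a median of 3474 bp, though merging peaks of several lists widens a region by itself. The medians were 1170 bp, 1025 bp and 933 bp for regions of ES1, ES2 and ES3 alone. These counts and their order depended on list length. With 12391 peaks per list from the top by score, 5233 regions were in ES1 alone, 4526 in ES2 alone, 4859 in ES3 alone and 2780 in all 3 lists, and the pairs ES1 and ES2, ES1 and ES3, and ES2 and ES3 held 2501, 1853 and 2451. By reads the counts were 3704, 3373, 3331 and 4290, and 2301, 1976 and 1970 for the pairs. With 6195 peaks per list by score they were 3459, 3419, 3603 and 751, and 1103, 875 and 901.

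**Figure D1:**
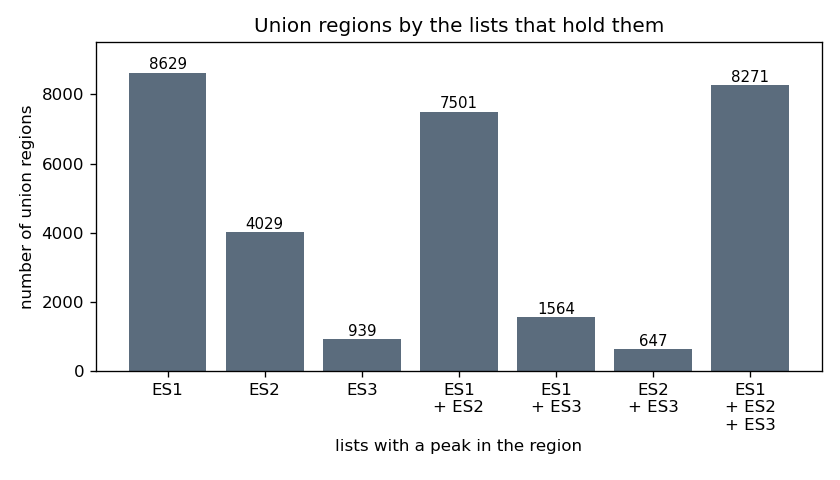
Bars give the number of merged regions (vertical axis) for each combination of lists with a peak in the region (horizontal axis). With the lists at their full, unequal lengths, regions in ES1 alone (8629) and in all 3 lists (8271) were the most numerous and those of ES2 and ES3 without ES1 (647) the fewest, an order that changed with lists of equal length.

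Peaks of shared regions had more reads, over longer inner intervals. Within ES1, peaks of regions in all 3 lists had medians of 22 reads, 2730.5 bp of width and 1543.5 bp of inner interval. Peaks in ES1 alone had 13 reads, 1170 bp and 914 bp. The median score, a relative read density, was not higher in peaks of regions in all 3 lists than in peaks of 1 list alone. It was 14.5 against 14.9 in ES1, 12.3 against 14.1 in ES2 and 12.5 against 15.3 in ES3. The median reads within ES2 were 19 for regions in all 3 lists and 13 for ES2 alone, and within ES3 15 and 12. Of the decile of ES1 peaks with the most reads (37 to 1087), 93.7% (92.7 to 94.6) overlapped ES2 and 78.1% (76.4 to 79.6) overlapped ES3. Of the decile with the fewest (6 to 10), 42.6% (40.7 to 44.5) overlapped ES2 and 23.0% (21.4 to 24.6) overlapped ES3. Peaks of the top decile were also wider, with a median of 5192.5 bp against 617 bp in the lowest, which favours overlap by at least 1 bp. The circular shifts were not divided by decile. In each of the 10 deciles the share found in ES2 exceeded the share found in ES3 by more than the intervals, ES2 being the longer list. With at least 50% of both peaks required, the top decile gave 59.2% in ES2 and 30.7% in ES3, the ninth decile 56.4% and 32.3%, and the lowest decile 21.5% and 12.0%, so the share found in ES3 no longer rose into the top decile. Some ES1 peaks with many reads were still missing elsewhere: 577 of the 2630 peaks in the top decile had no ES3 peak and 165 had no ES2 peak.

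**Figure D2:**
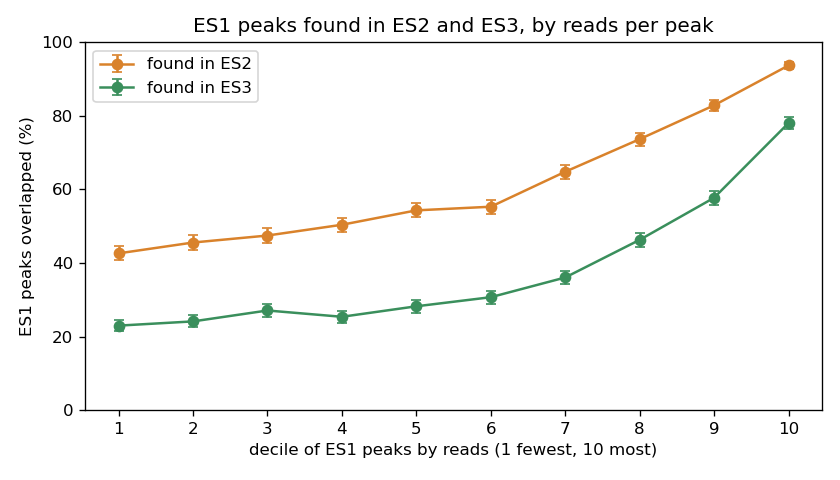
Points give the percent of ES1 peaks overlapped by a peak of ES2 or ES3 (vertical axis) in each decile of ES1 peaks ordered by reads (horizontal axis), with exact binomial 95% intervals as bars. Both shares were higher in the top decile (93.7% and 78.1%) than in the bottom decile (42.6% and 23.0%).

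Wide ES1 domains met a peak of the other lists more often than narrow peaks did, and more of their bases were covered. Of the 2616 ES1 peaks of at least 5 kb, 95.4% (94.5 to 96.1) met an ES2 peak and 79.7% (78.1 to 81.2) an ES3 peak. Of the ES1 peaks under 5 kb, 57.3% and 33.0% did. A wider peak also meets another list more often by chance: circular shifts gave 8.16% in ES2 and 4.76% in ES3 at 5 kb or more, and 3.42% and 1.82% below. Among the 558 ES1 peaks of at least 10 kb, 557 met an ES2 peak and 538 an ES3 peak. ES2 peaks covered 68.3% of the bases of these widest domains and ES3 peaks 41.9%, against 45.2% and 23.6% of the bases of ES1 peaks under 5 kb. Wider peaks also held more reads, with a median of 42 at 5 kb or more and 15 below.

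Several regions stood out by width or by reads within a combination of lists. The widest region called in ES1 alone was chromosome 11, 62258010 to 62267283, with 85 reads (67.9 to 105) over 9274 bp. Reads are known only for the inner interval, which can be a small part of a wide peak. The next widest of ES1 alone, of 9215 bp and 8992 bp, held 9 and 12 reads in inner intervals of 606 bp and 839 bp. The widest of ES2 alone (6212 bp) and of ES3 alone (3672 bp) held 13 and 10 reads in inner intervals of 1417 bp and 1378 bp. The reads in the rest of these peaks are unknown. Other regions of ES1 alone with many reads were chromosome 2, 26456921 to 26464105, with 63 reads (48.4 to 80.6), and chromosome 11, 51432743 to 51439475, with 62 reads (47.5 to 79.5). In ES2 alone the most reads lay at chromosome 11, 115363209 to 115367697, with 53 reads (39.7 to 69.3). In ES3 alone they lay at chromosome 9, 63773712 to 63777179, with 28 reads (18.6 to 40.5). A list has no value where it has no peak, so the level of the other lists at these regions is unknown.

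Among the regions shared by ES1 and ES2 and without an ES3 peak, the widest was chromosome 4, 154556449 to 154576443, a span of 19995 bp with 89 reads (71.5 to 110) in ES1 and 71 (55.5 to 89.6) in ES2. Chromosome 3, 34650071 to 34668788, followed with 18718 bp. There the ES2 inner intervals held 102 reads (83.2 to 124) over 12285 bp, and the ES1 peak of 16122 bp had an inner interval of only 500 bp with 9 reads (4.12 to 17.1). The widest region of ES2 and ES3 without ES1 was chromosome 8, 113328013 to 113334559, with 58 reads (44.0 to 75.0) in ES2 and 21 (13.0 to 32.1) in ES3. The widest of ES1 and ES3 without ES2 was chromosome 5, 122959118 to 122969685, with 91 reads (73.3 to 112) in ES1 and 23 (14.6 to 34.5) in ES3. The reads of different lists here come from inner intervals of different lengths.

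The widest region in all 3 lists was chromosome 11, 3023109 to 3099759, a span of 76651 bp. ES3 covered 75440 bp of it with 2 peaks and 1679 reads (1600 to 1761), and ES1 covered 68730 bp with 3 peaks and 969 reads (909 to 1032). ES2 covered 76578 bp with 1 peak, whose inner interval of 717 bp held 12 reads (6.20 to 21.0). The sequence of this region was not analysed here, so it is not shown to be a domain of the mark. Chromosome 12, 111707558 to 111761972, was called in all 3 lists in another proportion. ES1 covered it with 1 peak of 54241 bp, ES2 with 7 peaks that summed to 33002 bp and ES3 with 6 peaks that summed to 16233 bp. A domain of 61405 bp on chromosome 8, 123028071 to 123089475, held 3 peaks in ES1, 6 in ES2 and 6 in ES3, which covered 53684 bp, 51643 bp and 37247 bp. Their inner intervals of 10407 bp, 12339 bp and 27980 bp held 130 (109 to 154), 132 (110 to 157) and 273 (242 to 307) reads.

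Chromosomes took similar shares of the 3 lists, with exceptions. Chromosome 6 held 5.93% of ES1 peaks (5.65 to 6.22), 6.31% of ES2 peaks (5.99 to 6.64) and 7.16% of ES3 peaks (6.71 to 7.63). Chromosome 8 held 5.82% (5.54 to 6.11), 6.61% (6.28 to 6.95) and 6.63% (6.20 to 7.09), but by covered length ES1 and ES3 were closer, at 6.84% and 7.09%. Chromosome 2 went in the other direction, with 7.38% (7.07 to 7.70), 6.66% (6.33 to 7.00) and 6.23% (5.81 to 6.67). The ES1 and ES3 intervals were apart on these 3 of the 20 chromosomes. By covered length, which has no interval, the largest difference between ES1 and ES3 was instead on chromosome 7, with 6.44% and 7.71%. Its intervals by peaks overlapped, at 6.45% (6.16 to 6.76) and 7.15% (6.70 to 7.62). Chromosome X held 1.57% (1.43 to 1.73) of ES1 peaks, 1.58% (1.42 to 1.76) of ES2 peaks and 1.23% (1.04 to 1.44) of ES3 peaks.

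**Figure D3:**
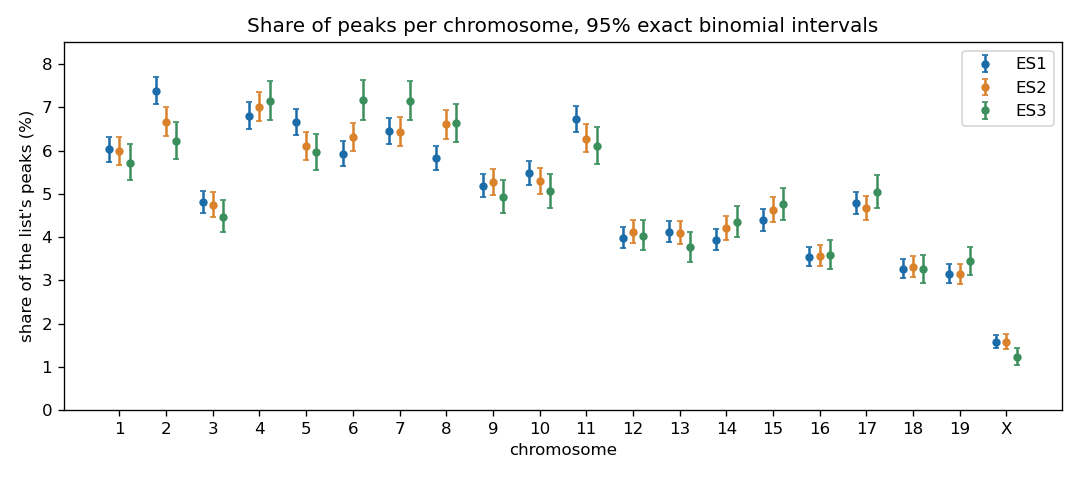
Points give each chromosome's share of a list's peaks in percent (vertical axis) for ES1, ES2 and ES3, with exact binomial 95% intervals as bars, along the chromosomes (horizontal axis). The ES3 share was above the ES1 share on chromosome 6 (7.16% against 5.93%) and below it on chromosome 2 (6.23% against 7.38%).

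Chromosome X stood apart in read density. It held 0.257 reads per kb in ES1, 0.327 in ES2 and 0.314 in ES3, or 0.262, 0.295 and 0.319 of the median autosome. Regions on X made up 0.798% (0.618 to 1.01) of the regions in all 3 lists, and 2.47% (2.15 to 2.82), 3.30% (2.77 to 3.90) and 3.83% (2.70 to 5.27) of the regions in ES1, ES2 and ES3 alone. The smallest peaks on X held 6 reads, against 8 to 10 on the autosomes. The authors' score is relative to the read density of each chromosome, and its ES1 median was 44.4 on X and between 10.0 and 19.1 on the autosomes.

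ES2 had a higher read density than ES1 on every chromosome, 1.04 to 1.16 times on the autosomes and 1.27 times on X, with a median of 1.12. That median mostly restates the larger total of ES2, 2717742 reads against 2441443 in ES1. ES3 had 0.898 to 1.06 times the density of ES1 on the autosomes, lowest on chromosome 11 and highest on chromosome 3, and 1.22 times on X. The ratio was lower on chromosomes where a larger share of ES1 reads fell in peaks, with Pearson's r = -0.92 and Spearman's rho = -0.86 across 20 chromosomes. ES1 reads in peaks enter both the ratio and the share, so a negative relation is partly built in. Without X and chromosome 17, the farthest from the median, r was -0.79 and rho -0.81. Chromosomes are not independent replicates, so no p-value is given.

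**Figure D4:**
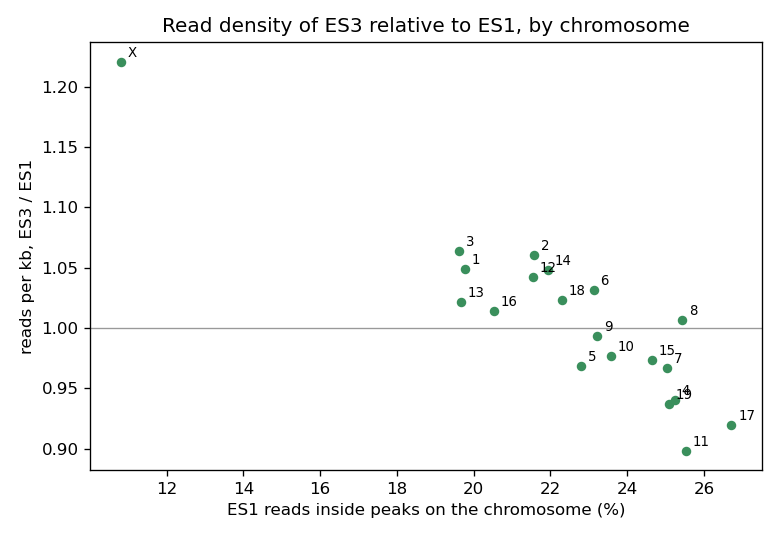
Each point is a chromosome, with the percent of its ES1 reads inside peaks (horizontal axis) and its reads per kb in ES3 divided by ES1 (vertical axis); the line marks equal density. Chromosome X lies at 10.8% and 1.22, and chromosome 11 at 25.5% and 0.898.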

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

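The alternatives were planned before the data were examined, except the shortening of the longer lists for overlaps, each ranking by reads, the 50% rule for deciles of reads, and the removal of the loci with the highest scores, which were chosen after. The order of the lists by peaks and covered length held with peaks as listed and merged. Merging peaks within 1 kb gave covered lengths of 64.1 Mb for ES1, 46.8 Mb for ES2 and 22.9 Mb for ES3 and left each count of peaks within 1.5 times. Autosomes alone kept all 6 overlap shares inside their intervals.

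The overlap of ES3 with ES1, of ES3 with ES2 and of ES2 with ES1 depended on the rule. Requiring 50% of both peaks gave 41.1%, 40.9% and 46.1%. Lists of 6195 peaks from the top by score gave 26.8%, 26.8% and 30.1%. Lists of 12391 peaks gave 39.7%, 43.8% and 43.5% by score, and 56.2%, 54.2% and 56.7% by reads. Fewer peaks per list lower an overlap by construction, and ranking by score favours narrow peaks, since width and score were related across peaks with Spearman's rho = -0.43 in ES1, -0.48 in ES2 and -0.54 in ES3. It also favours chromosomes of low read density, since the score is relative to its chromosome, with an ES1 median of 44.4 on X and 10.0 on chromosome 11. The lead of ES1 over ES2 as the closer list to ES3 was lost under both score rankings and shrank with the 50% rule and with ranking by reads.

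Regions in ES1 alone numbered 3459 with 6195 peaks per list, 5233 with 12391 peaks by score and 3704 by reads. Regions in ES3 alone numbered 3603, 4859 and 3331 in these settings, and regions in all 3 lists 751, 2780 and 4290. The excess of ES1-only over ES3-only regions thus shrank with equal lengths in both settings of 12391 peaks and turned with 6195. By covered length, chromosome 8 took 6.84% of ES1 and 7.09% of ES3. ES3 stayed above ES1 on chromosomes 6 and 8 and below it on chromosome 2. Chromosome 7, not among the 3 chromosomes apart by peaks, differed more by covered length, with 6.44% of ES1 and 7.71% of ES3. Without 9 loci that are among the 10 highest scores of every list, reads inside peaks were 22.8%, 15.7% and 8.64% in ES1, ES2 and ES3. Of all 79 values computed under an alternative, 28 stayed within the interval or within 1.5 times the main count and 48 did not. The other 3 are the merged covered lengths above, which have no interval.

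The alternatives for promoter shares, genes with a promoter peak and gene lists were not run, since no annotation of mm9 was used here. No paired analysis was possible because the peak lists carry no replicate numbers and no test between groups of libraries was run. Depth limits which regions can be called: with about 1 read per kb on the autosomes, the fewest reads seen behind a peak were 8 to 10, by chromosome. A region missing from a list is not shown to be unmarked in those cells.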

Other observations

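The tests in this part were all chosen after the pattern they bear on was seen, and the lists are tied to no labelled group, so no biological explanation was tested other than an extra copy of chromosome 6.

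The same few places carried the highest scores in every list. Regions with a peak among the 10 highest scores of all 3 lists numbered 9, and they held 0.604% of the in-peak reads of ES1, 1.17% of ES2 and 2.75% of ES3. At chromosome 12, 3109698 to 3110831, reads numbered 414 (375 to 456) in ES1, 772 (718 to 828) in ES2 and 1085 (1021 to 1152) in ES3, each over an inner interval of 501 bp. Chromosome 6, 103598864 to 103599400, gave 186 (160 to 215), 293 (260 to 329) and 397 (359 to 438) over 500 bp. At chromosome X, 139917339 to 139917841, the reads were 67 (51.9 to 85.1), 121 (100.4 to 145) and 159 (135 to 186) over 500 bp. These places thus had more reads in ES3 than in ES1 although the totals of ES1 and ES3 were nearly equal. Other places of the kind did not: chromosome 17, 39979946 to 39985727, had 1087 (1023 to 1154) reads in ES1 and 960 (900.2 to 1023) in ES3, and chromosome 15, 74915939 to 74917354, had 387 (349 to 428) and 272 (241 to 306). The sequence at these places was not analysed here.

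ES3 held 12391 peaks against 26292 in ES1, although fewer reads behind the ES3 list would lower its read density and the median over 20 chromosomes of ES3 over ES1 was 1.01. A higher minimum of reads per peak in ES3 would raise the smallest number of reads behind a peak, and this was higher in ES3 on 0 of 20 chromosomes. The lowest score was 5.05 in ES1 and 5.92 in ES3, but a stricter score cut would account for few of the missing peaks, since 0.764% of ES1 peaks lay under the lowest ES3 score of their chromosome and class of inner length. A smaller share of ES3 reads in enriched regions, with the rest spread evenly, stays possible. It predicts a density ratio that falls where ES1 has more of its reads in peaks, and Spearman's rho was -0.86. That value cannot decide the question, since ES1 reads in peaks enter both the ratio and the share. What lowers the number of ES3 peaks stays open. The cells' chromatin, the yield of the immunoprecipitation, the number of cells and the rule that put cells into a list could each contribute. They cannot be told apart, since no value of a single cell or library was analysed here. The shares of reads inside peaks are counted over each list's own peaks, so they partly restate its number of peaks.

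Chromosome 6, picked as the highest of 20, kept 46.3% (43.8 to 48.8) of its 1559 ES1 peaks in ES3, against 37.1% on the other chromosomes. An extra copy of chromosome 6 in most ES3 cells would raise its read density, but its ES3 over ES1 ratio was 1.03 times the median of the other autosomes; a gain in a small part of the cells is not excluded. Chromosomes with more reads per ES1 peak could keep more of their peaks. Over 20 chromosomes the ratio of peak shares, ES3 over ES1, rose with the mean reads per ES1 peak. Pearson's r was 0.51 and Spearman's rho 0.39. The reads of the chromosome 6 peaks gave an expected 38.7%, below the interval of the observed percent and nearer to the 37.1% of the other chromosomes. But the interval covers counting error and not the spread between chromosomes. The expected percent also lay outside it on chromosomes 2, 5, 7, 9, 10, 11, 14, 16 and X. Chromosome 6 is therefore not shown to lie outside that spread. A calling threshold set per chromosome stays open: on the 10 other chromosomes with the same smallest number of reads per peak, 9, the found percent exceeded the expected by at most 3.33 points, against 7.63 on chromosome 6, but their intervals reach 5.72 and that of chromosome 6 starts at 5.13. Over all 20 chromosomes the difference ran from -6.96 to 7.63 points, with 5.28 on chromosome 14 and 3.83 on chromosome 16, where the smallest peaks held 8 reads.

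Chromosomes 11, X and 2 deviated most in the other direction, followed by 5, 9 and 10. On chromosome 11, 34.6% (32.4 to 36.9) of ES1 peaks were found in ES3, with 41.6% expected from their reads. On chromosome 2 the values were 32.7% (30.6 to 34.9) and 38.7%, and on X 21.3% (17.4 to 25.5) and 27.6%.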
